A study of Mus musculus with 12 samples.

How the data were processed

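The samples were 12 hybridizations of pooled mouse hippocampal RNA, with 3 arrays in each of 4 groups (control or mutant, saline or kainate). Per the labels' protocols, animals received 20 mg/kg kainate or saline, were killed after 1 h, and the RNA of 3 animals was combined before biotin labelling. Replicates are described in the labels as biological, and the groups share the replicate numbers 1, 2 and 3.

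The deposited table held 1 value per probe set and array on a log2 scale, which the authors made with R 2.4.1 and GCRMA, per the submitters' processing notes. GCRMA corrects background by probe sequence and summarises the probes of a set. The settings, the genome build and the annotation used by the authors are not given in the sources used here, and scanner files were not used here. The log2 scale and the lack of centring per probe set were judged from the values, which ran from -1.05 to 13.3. All columns of the table were used. Of 12477 table entries, 66 were Affymetrix control probe sets, leaving 12411. No coordinates are printed. A table of the GRCm38.p6 annotation served for gene names and neighbours alone. In the platform annotation 10581 probe sets had 1 gene symbol, 178 had several and 1652 had none, and 10550 matched the gene table by Entrez identifier, with 0 symbols changed. No gene was named from a probe set with several symbols.

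Probe sets with a value over 4 in at least 3 of the 12 arrays were tested, which left 6334, of which 5925 had 1 symbol. A linear model with 1 mean per group was fitted over all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), and p-values were adjusted by Benjamini-Hochberg at 0.05 within each comparison. The 5 planned comparisons were kainate against saline in each genotype, their difference, and mutant against control with each treatment. The comparisons averaged over genotypes or treatments, fits of replicates 2 and 3 alone, and the block combined with quantile normalization were added after the data were seen. The tests, the alternatives not named as added, the gene lists and the rule for named genes were fixed before the data were examined.

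The check of pairing used each array's deviations from its group mean over all tested probe sets. All 18 pairs of arrays with the same number in different groups correlated above 0.1, with r from 0.361 to 0.881, and each of the 12 arrays correlated best with an array of its own number. Principal components were taken from the log2 values and not from the deviations. The first took 52.8% of the variance and set the arrays numbered 1 apart, with negative scores against positive ones. The second took 19.2% and mainly parted saline from kainate arrays of the other numbers, so it is not a measure of pairing. Arrays numbered 2 and 3 in different groups also correlated, with r from 0.309 to 0.583, a range that overlaps that of shared numbers. The numbers therefore pair the arrays mainly by setting number 1 apart, and the pairing within numbers 2 and 3 is weaker. Values with the replicate number as a block are given where they change a call or a count. The labels do not say what a number stands for. Array correlations lay between 0.910 and 0.991 and no pair of arrays was identical.

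Named genes were the largest log2 changes among probe sets that passed, had 1 symbol and had values that did not overlap between both groups of 3 arrays, up to 15 rising and 10 falling for kainate in controls and fewer for the other comparisons, and the 5 smallest p-values where fewer than 5 passed. The same rule was applied to the fits with a block, as an addition made after the data were seen. For the averaged genotype comparison, also added then, the rule was used without the condition that values do not overlap. For 3 against 3 arrays chance alone separates the values of 10% of probe sets. A gene with several probe sets is given by the one with the largest change among those that passed, and other probe sets are quoted for part of these genes.

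Of 24 lists of genes on activity-dependent transcription, CREB function, metabolism, stress, excitability and cell types, 21 had at least 3 measured genes. They were tested with fry, which asks whether a group moves on balance in one direction, over the 5 comparisons (105 tests adjusted together), with the averaged comparisons as a family of their own. A gene was represented by its probe set with the highest mean. The camera test with an estimated correlation between genes was the alternative, and of 6 calls by fry it kept 4, the immediate early group in both genotypes, the feedback group in labelled mutant arrays and the astrocyte group with saline. With the block and an estimated correlation none of the 6 was kept. The size of the response and RNA quality were tested by exact two-sided permutation, and the 12 RNA quality tests were adjusted together. The RNA quality permutations did not keep arrays within their pairs.

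The calculations were tested on simulated data. For kainate in control animals, with 6334 probe sets, the fit without a block recovered 28%, 60%, 96% and 96% of 50 probe sets changed 1.5-fold, 2-fold, 4-fold and 8-fold, with 3 false calls, and the fit with a block recovered 70%, 82%, 100% and 100%, with 8 false calls. The list test found 20 of 20 shifted lists and 0 of 20 unshifted ones. The simulated genes of a list varied independently, so this does not show the error rate for lists of correlated genes. All simulated data took replicate effects and spread from the fit with a block, so the gain with the block was built in. In the real arrays the kainate changes depended on the replicate number, which the simulation left out. Its recovery and false calls may therefore not hold for the real fits. Median log2 changes over the tested probe sets were -0.0555 for kainate in control and -0.0278 in labelled mutant arrays. Over all probe sets, dim ones included, the median was 0.141 for kainate in control animals and -0.189 for the difference of responses, and within 0.1 of 0 for the other 3 planned comparisons, so the changes of tested probe sets are given as measured. Alternatives covered the filter, the variance model, array weights, scaling, the block, the arrays entering the fit, a fold threshold and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.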

Results

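Gene expression was measured in the mouse hippocampus 1 h after an intraperitoneal injection of kainate, a glutamate receptor agonist that evokes seizures, or of saline. Control animals were compared with mutant animals, and the series title names the loss of CREB and CREM, which are cAMP-responsive transcription factors, as the mutation studied. The design formed 4 groups, namely control with saline, control with kainate, labelled mutant with saline and labelled mutant with kainate, with 3 arrays in each. Each array carried RNA pooled from 3 animals, so the 12 arrays are separate pools and not single animals. The arrays were Affymetrix MG-U74B arrays, and the deposited values were GCRMA summaries on a log2 scale. Array medians lay between 3.77 and 4.07, and between 5741 and 6378 of 12411 probe sets had a value over 4. The number of arrays limits the precision of every value below. Fold changes refer to log2 differences between group means, and 6334 probe sets were tested.

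The targeted genes were examined first. The Creb1 probe set was higher, not lower, in the arrays labelled mutant. Its mean log2 value was 7.35 ± 0.35 (SD, n = 3) in control saline arrays and 8.23 ± 0.117 in labelled mutant saline arrays. After kainate it was 6.98 ± 0.154 in control arrays and 7.97 ± 0.439 in labelled mutant arrays. The difference was 0.89 (1.85-fold) with saline and 0.99 (1.99-fold) with kainate. Neither passed the test over all probe sets (limma adjusted p = 0.523 and 0.391), also with the replicate number as a block (0.0751 and 0.0545). Averaged over both treatments, a comparison added after the data were seen, the Creb1 difference was 0.94 (adjusted p = 0.0502) and it passed with the block (0.00413). The Crem probe set was at background in every group, with means from 2.93 to 3.16, and was below the level required for testing. Where the Creb1 probes lie relative to the deleted part is not given in the sources used here, so neither probe set checks the loss of the proteins, and the arrays are called labelled mutant throughout.

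The first comparison asked which transcripts kainate changed in the control hippocampus. Within 1 h, the genes that rose included single inhibitors of growth factor and MAP kinase signalling and single immediate early transcription factors. The largest rise was that of Dusp5, a nuclear phosphatase that inactivates ERK, at 2.37 (5.17-fold, SE 0.115, adjusted p = 5.21e-06). Csrnp1, an immediate early nuclear factor, rose by 2.35 (5.08-fold, SE 0.189, adjusted p = 0.000438), and Maff, a small Maf transcription factor, rose by 2.15 (4.44-fold, SE 0.271, adjusted p = 0.0099). Spry2, an inhibitor of receptor tyrosine kinase signalling, rose by 1.29 (2.45-fold, SE 0.165), Rgs4, which accelerates GTP hydrolysis by G proteins, by 1.10 (2.14-fold, SE 0.107), and the AP-1 subunit Fosl2 by 1.03 (2.04-fold, SE 0.158). The pseudokinase gene Trib1 rose by 2.24 (4.74-fold), the circadian repressor Ciart by 1.81 (SE 0.216) and the histone chaperone gene Spty2d1 by 1.77 (3.42-fold; second probe set 0.35). Acsl4, an arachidonate-activating acyl-CoA synthetase, fell by 0.96 (1.95-fold, SE 0.138, adjusted p = 0.0237). Each of these 10 genes changed in the same direction in all 3 replicate numbers, which the rule for named genes fixes, since their values may not overlap between groups. The calls of Trib1 and Fosl2 were lost in 10 and that of Acsl4 in 8 of the 12 fits that left out 1 array.

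Among the gene groups fixed in advance, immediate early transcription factors rose in control animals (fry adjusted p = 4e-04, and adjusted p = 0.0293 with an estimated correlation). With the block and an estimated correlation this group did not pass (adjusted p = 0.0737). Of 11 measured members, 3 passed over all probe sets (Csrnp1, Maff and Fosl2) and 6 passed when adjusted over the list alone, including Fbxo33 at 0.96 and the orphan receptor gene Nr4a3 at 0.54. Negative feedback genes of kinase signalling also rose (adjusted p = 0.000903), with 2 of 15 members passing (Dusp5 and Spry2) and 3 when adjusted over the list alone. For this group the adjusted p was 0.139 with an estimated correlation between genes. CREB target genes moved upward as a group (adjusted p = 0.0433, and adjusted p = 0.361 with an estimated correlation), although none of 15 passed over all probe sets and 2 passed when adjusted over the list alone (Vgf at 1.00 and Nr4a3). Of 25 measured activity-regulated effector genes, Trib1, Spty2d1 and Rgs4 rose, and the group did not pass (adjusted p = 0.227). Most genes listed for the immediate early, CREB target and effector groups were not among the measured ones. Results for these groups therefore cover only a part of each list. Interneuron markers passed only with the replicate number as a block (adjusted p = 0.0393 against 0.251 without it, and adjusted p = 0.611 with the block and an estimated correlation). No one of these 6 genes passed over all probe sets, and 3 were lower when adjusted over the list alone, among them Maf (-0.70), Gad2 (-1.26) and Cnr1 (-0.44). Markers of choroid plexus, a tissue next to the hippocampus, had a median change of -0.46 over 6 genes and did not pass (adjusted p = 0.41).

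In total 10 probe sets passed in control animals, 9 higher and 1 lower, by limma with Benjamini-Hochberg adjustment. With the replicate number as a block 37 passed, 17 higher and 20 lower, and these included all 10. With the block and quantile normalization 25 passed, 16 higher and 9 lower. Among the genes added by the block, Dot1l, a histone H3 methyltransferase, rose by 1.17 (adjusted p with the block = 0.0197), the corepressor gene Irf2bp2 by 1.06 (0.0351) and the neuropeptide precursor gene Vgf by 1.00 (0.0351). Among genes that fell with the block were Mllt10, which encodes a partner of Dot1l (-1.63, adjusted p = 0.0188), Zbtb14 (-1.24), Mtmr4 (-1.19), Naa50 (-1.14), Zcchc14 (-0.87), Dbt (-0.78), Cdc37l1 (-0.75), Mex3c (-0.73) and Timm29 (-0.71). Other probe sets of Zcchc14 (-0.32), Mtmr4 (-0.75), Timm29 (-0.44), Naa50 (-0.14 and 0.26), Dbt (0.06), Cdc37l1 (0.10, 0.21 and 0.18) and Zbtb14 (-0.11) gave smaller changes or changes of the other sign, so these falls refer to single probe sets. When 1 array was left out at a time, 4 to 14 probe sets passed, the fewest without replicate 1 of control saline or replicate 2 of control kainate.

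The second comparison asked for the kainate response in the arrays labelled mutant. The same signalling inhibitors and transcription factors led it. Maff rose by 2.65 (6.30-fold, SE 0.271, adjusted p = 0.00219), Dusp5 by 2.65 (6.28-fold, SE 0.115, adjusted p = 1.65e-06), Trib1 by 2.52 (5.74-fold, SE 0.351, adjusted p = 0.0188) and Csrnp1 by 2.04 (4.10-fold, SE 0.189, adjusted p = 0.00116). Spry2 rose by 1.43 (2.69-fold), the FOXO-induced gene Depp1 by 1.48 (2.79-fold), Dusp4, a further MAP kinase phosphatase, by 1.37 (2.59-fold, SE 0.152, adjusted p = 0.00383) and Vgf by 1.35 (2.54-fold, SE 0.2, adjusted p = 0.0247). The remaining 3 that passed, Rgs4 at 1.30, Fosl2 at 1.06 and Ccdc86 at 0.94, lay outside the rule for named genes and are named because the list is short.

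Immediate early transcription factors rose as a group in labelled mutant arrays (fry adjusted p = 0.000493, and adjusted p = 0.0737 with the block and an estimated correlation), with Csrnp1, Maff and Fosl2 passing among 11 genes. Adjusted over the list alone, 5 were higher and 1 probe set of Srf was lower at -0.69, while the other Srf probe sets gave 0.73 and 0.60. Negative feedback genes rose as well (adjusted p = 0.000493, and adjusted p = 0.137 with the block and an estimated correlation), with Dusp4, Dusp5 and Spry2 passing among 15 and 4 passing when adjusted over the list alone, the fourth being Spry1 at 0.82. Among 25 activity-regulated effector genes Rgs4, Trib1 and Vgf rose, and the group passed only with the block (adjusted p = 0.0291 against 0.12, and adjusted p = 0.287 with the block and an estimated correlation). CREB target genes gave an adjusted p of 0.0854, or 0.0449 with the block (adjusted p = 0.456 with the block and an estimated correlation), and Vgf was the single member of 15 that passed over all probe sets. Their median change was about 0 (-0.000368) while their mean was 0.133.

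In labelled mutant arrays 11 probe sets passed, all of them higher, and 23 passed with the block, 18 higher and 5 lower, including the 11. The block added the synaptic scaffold gene Homer1 at 1.49 (2.80-fold, adjusted p = 0.0154 with the block) through 1 of its probe sets. The second Homer1 probe set gave -0.11, and the gene is known to produce a short transcript after activity besides the long one. The block also added falls of Kctd4 (-1.04, adjusted p = 0.014), Magt1 (-0.75, adjusted p = 0.0296; other probe sets -0.64 and 0.11) and Tmem106b (-0.57, adjusted p = 0.014; other probe sets -0.32 and -0.11). Leaving out 1 array at a time gave 6 to 17 probe sets, the fewest without replicate 2 or 3 of labelled mutant kainate and the most without its replicate 1.

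**Figure D1:**
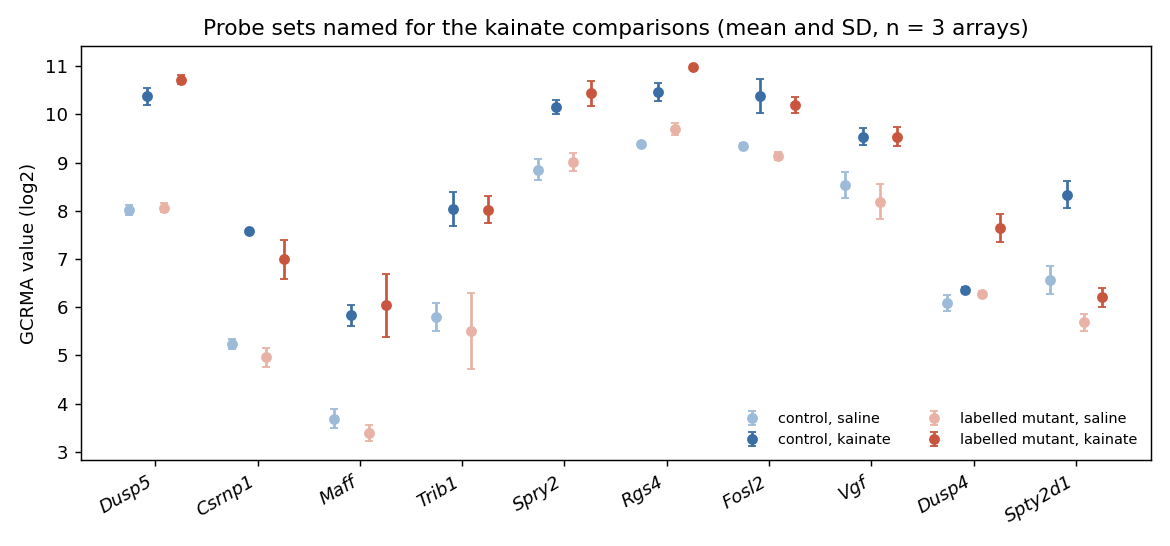
Mean GCRMA value (log2, vertical axis) of 10 genes in each of the 4 groups, with bars of 1 SD over n = 3 arrays. Dusp5, Csrnp1, Maff and Trib1 stood at least 2.04 higher with kainate than with saline in both genotypes, while Dusp4 and Spty2d1 differed between genotypes among the kainate arrays.

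The third comparison, the question of the series title, asked whether the kainate response differed between genotypes. Of the 9 rises in control and 11 in labelled mutant arrays, 7 were shared, against 0.0156 for independent lists. The shared genes were Dusp5, Csrnp1, Trib1, Maff, Spry2, Rgs4 and Fosl2. With the block 13 rises were shared of 17 and 18, against 0.0483, and none of the 20 and 5 falls was shared, against 0.0158. Across 6334 probe sets, which are not independent replicates, the changes in both genotypes had a correlation of 0.625. By replicate number it was 0.106, 0.749 and 0.419, so it rested on replicates 2 and 3. No probe set passed the test of the difference itself by limma, and 147 had an unadjusted p under 0.05. With the block none passed either, and 566 had an unadjusted p under 0.05. The smallest p belonged to Dusp4, whose change was larger by 1.11 in labelled mutant arrays (SE 0.216, adjusted p = 1, with the block 0.281), followed by Ccdc86 (0.95), Spty2d1 (-1.26, with the block 0.281), Unc13c (-0.52) and Acsl4 (0.70). None of these 5 passed. The second probe sets of Dusp4 and Spty2d1 gave differences of -0.20 and -0.47. None of the 21 gene groups passed for the difference of responses, with immediate early transcription factors at an adjusted p of 0.591 and CREB target genes at 0.835. Most genes listed for these 2 groups were not measured, so their response was not compared here.

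The size of the response was also compared as 1 score per array over the 26 probe sets that passed for kainate averaged over genotypes. The mean signed change was 1.16 ± 0.0324 (SD over 3 replicate numbers) in control and 1.18 ± 0.149 in labelled mutant arrays. The difference of 0.021 was not larger than the spread (exact two-sided permutation p = 0.82, 400 permutations). In simulated data made from these arrays, the test of the difference of responses recovered 8% of 1.5-fold, 36% of 2-fold and 82% of 4-fold differences, or 32%, 60% and 98% with the block, so most differences of 1.5-fold would be missed with 3 arrays per group. The simulated data followed the model with a block, which favours the second set of values.

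The fourth comparison asked what differed between genotypes without kainate. No probe set passed by limma, and 246 had an unadjusted p under 0.05. With the replicate number as a block 9 probe sets passed, 1 higher and 8 lower in labelled mutant arrays, and 570 had an unadjusted p under 0.05. With the block and quantile normalization, an addition made after the data were seen, only Tspyl3 passed, so 8 of these 9 calls depend on the scaling. Thbs4, a matricellular protein of the thrombospondin family, was 2.83-fold higher (adjusted p with the block = 0.0423). Lower were Tspyl3 (-1.41, adjusted p with the block = 0.0015), the palmitoyltransferase gene Zdhhc3 (-1.30 and -0.62 for 2 probe sets that passed), Fahd2a (-1.20), Smim19 (-0.99), the zinc finger factor gene Bcl11b (-0.91), Tmem200a (-0.86) and Nbdy (-0.65), which encodes a microprotein of processing bodies. Other probe sets gave -0.49 and 0.04 for Bcl11b and -0.31 and 0.03 for Zdhhc3. Without the block, Tmem200a and the second Zdhhc3 probe set had the smallest adjusted p (0.124).

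Astrocyte markers were higher as a group in labelled mutant saline arrays (fry adjusted p = 0.0106, and adjusted p = 0.0304 with an estimated correlation). With the block and an estimated correlation the call was lost (adjusted p = 0.0782). Of 16 measured genes 15 lay above 0, with a median of 0.20, and the water channel gene Aqp4 (0.44, adjusted p = 0.0424 over the list alone) was the one member that passed over the list alone. None passed over all probe sets. Principal neuron markers had a median of -0.20 over 12 genes and did not pass (adjusted p = 0.0677). The astrocyte call ended when each array was centred on its median (adjusted p = 0.0866).

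The fifth comparison set labelled mutant against control arrays after kainate, where 4 probe sets passed, 2 higher and 2 lower. Spty2d1 was lower in labelled mutant arrays by the largest margin (-2.13, 4.39-fold, SE 0.193, adjusted p = 0.00273). The f suffix of its probe set marks probes shared within a sequence family, and a second probe set gave -0.32. Nbdy was lower (-0.86, 1.81-fold, SE 0.111, adjusted p = 0.0196). Dusp4 was higher by 1.30 (2.46-fold, SE 0.152, adjusted p = 0.0108) through 1 probe set, while its second probe set gave -0.03. The nucleolar protein gene Ccdc86 was higher by 1.18 (2.26-fold, SE 0.138, adjusted p = 0.0108). With the block 7 probe sets passed, including the 4, and the block added Tspyl3 (-1.12, adjusted p = 0.00366), Tmem200a (-0.81, adjusted p = 0.0297) and Zcchc18 (-0.64, adjusted p = 0.00994), the last outside the rule for named genes and given because the list is short. Leaving out 1 array at a time gave 1 to 5 probe sets, and 1 passed without replicate 2 of control kainate or replicate 3 of labelled mutant kainate. Centring each array on its median left 1, a lower one.

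No gene group passed without the block after kainate. With the block, immediate early transcription factors were lower in labelled mutant arrays (adjusted p = 0.0135 against 0.0619, and adjusted p = 0.255 with the block and an estimated correlation), with members at -0.63 (Nr4a2), -0.59 (Csrnp1) and -0.31 (Nr4a3). CREB target genes were lower too (adjusted p = 0.0212 against 0.127, and adjusted p = 0.456 with the block and an estimated correlation), and Nr4a2 and Nr4a3 belong to both groups. Voltage-gated ion channels were lower (adjusted p = 0.0393 against 0.12, and adjusted p = 0.341 with the block and an estimated correlation), with Kcna1 at -0.50 and Scn4b at -0.53. Astrocyte markers were higher (adjusted p = 0.0251 against 0.0619, and adjusted p = 0.255 with the block and an estimated correlation), with Aqp4 at 0.44 and Mlc1 at 0.37. None of these members passed over all probe sets.

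The genotypes were also compared with saline and kainate averaged, a comparison added after it was seen that replicate numbers pair the arrays. It gave 16 probe sets, 4 higher and 12 lower in labelled mutant arrays, and 147 with the block, 51 higher and 96 lower, including the 16. With the block the largest rises were those of Mmab, an enzyme of cobalamin metabolism (1.46, SE 0.203, adjusted p = 0.00893), Thbs4 (1.44, SE 0.159, adjusted p = 0.00319) and Plek, the pleckstrin gene of leukocytes and microglia (1.24, SE 0.169, adjusted p = 0.00807). Slc14a1, a urea transporter gene, was higher by 0.91 and the receptor gene Tgfbr1 by 0.70. The largest falls were those of Spty2d1 (-1.51, adjusted p = 7.56e-05; second probe set -0.08), the talin gene Tln2 (-1.42, adjusted p = 0.00937), Tspyl3 (-1.27, adjusted p = 7.56e-05), Zdhhc3 (-1.14), Fahd2a (-1.11) and Trmt61b (-1.05), with Coq2 (-0.94) and Bcl11b (-0.84) among those that followed. Leaving out 1 array at a time without the block gave 3 to 16 probe sets, and 3 passed without replicate 3 of control saline, replicate 2 of labelled mutant saline or replicate 3 of labelled mutant kainate.

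In the averaged comparison immediate early transcription factors were lower in labelled mutant arrays (fry adjusted p = 0.0223, and adjusted p = 0.0472 with an estimated correlation), a call lost with the block and an estimated correlation (adjusted p = 0.149). Their median was -0.185, 2 of 11 lay above 0, and Nr4a2 (-0.54) and Nr4a3 (-0.28) passed over all probe sets with the block. CREB target genes were lower as well (adjusted p = 0.0276, and adjusted p = 0.184 with an estimated correlation), with a median of -0.108 over 15 genes and the same 2 members passing. Astrocyte markers were higher (adjusted p = 0.00396, and adjusted p = 0.014 with an estimated correlation), with 15 of 16 above 0, a median of 0.181, and Aqp4 (0.44) and Mlc1 (0.36) passing with the block. Principal neuron markers were lower (adjusted p = 0.0133, and adjusted p = 0.0885 with an estimated correlation), and Fibcd1, a CA1 marker (-0.62), and the ephrin receptor gene Epha7 (-0.55) passed with the block (adjusted p = 0.0328 and 0.0313). Microglia markers were higher only with the block (adjusted p = 0.0241 against 0.0838, and adjusted p = 0.241 with the block and an estimated correlation), with Olfml3 at 0.62 and Siglech at 0.61. Endothelial and mural markers were also higher only with the block (adjusted p = 0.0268 against 0.185, and adjusted p = 0.303 with the block and an estimated correlation), with Ednrb at 0.36.

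**Figure D2:**
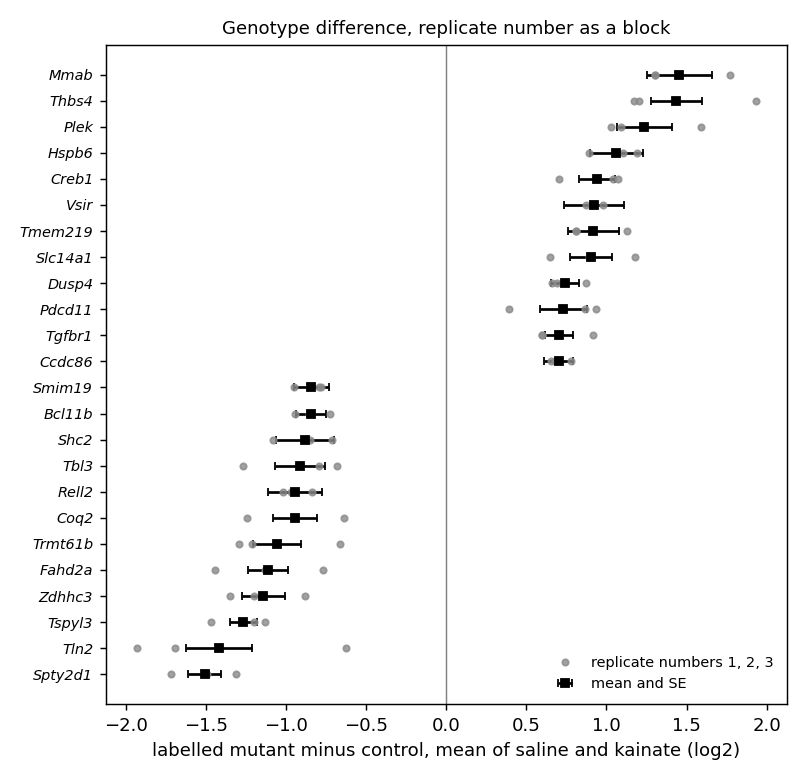
Difference between labelled mutant and control arrays (log2, horizontal axis), averaged over saline and kainate, for the 24 genes named for this comparison. Grey points are the 3 replicate numbers and black squares with bars are the mean and SE of the fit with the replicate number as a block, from 1.46 for Mmab to -1.51 for Spty2d1.

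Arrays of the same replicate number resembled each other, and the 4 arrays of replicate 1 stood apart from the other 8. Their spiked-in bacterial control transcripts, which contain no mouse RNA, averaged 9.03 against 10.3 (difference -1.27, exact permutation p = 0.00202, adjusted p = 0.0242), and their Gapdh 3' minus 5' signal, a measure of RNA integrity, differed by -0.19 (exact permutation p = 0.00404, adjusted p = 0.0242). Over all replicates, the difference in the Gapdh measure was 0.0754 between kainate and saline (exact permutation p = 0.299) and -0.0173 between genotypes (exact permutation p = 0.814). For the actin measure it was 0.000167 and -0.0692 (p = 1 and 0.335, both by exact permutation). Within replicates 2 and 3, the Gapdh measure differed between kainate and saline by 0.127 (exact permutation p = 0.0286, adjusted p = 0.0858) and the spiked-in controls by -0.53 (exact permutation p = 0.0286, adjusted p = 0.0858). When only replicates 2 and 3 were used, an alternative added after the data were seen, 637 probe sets passed for kainate in control and 596 in labelled mutant arrays. Pooled over genotypes, 1412 passed in replicates 2 and 3, with median changes of 0.50 for the 555 higher and -0.57 for the 857 lower. In replicate 1, which had no part in their choice, the same probe sets had medians of -0.01 and -0.05.

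**Figure D3:**
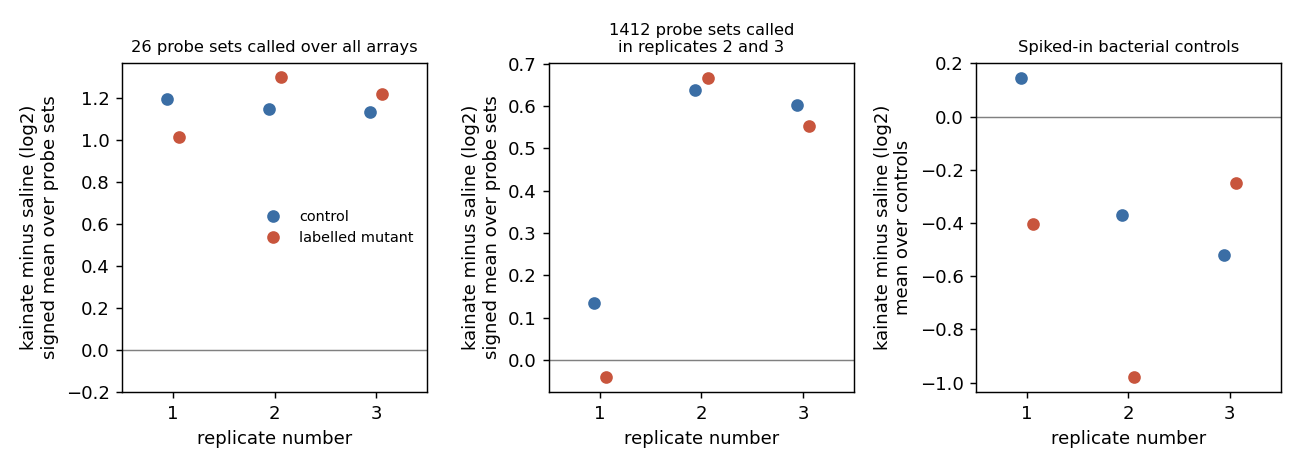
Kainate minus saline (log2, vertical axes) in each pair of arrays, by replicate number and genotype, for the 26 probe sets that passed over all arrays, the 1412 that passed in replicates 2 and 3, and the mean of the spiked-in bacterial controls. The first set changed by between 1.01 and 1.30 in all 6 pairs, while the second changed by 0.55 to 0.67 in replicates 2 and 3 and by 0.13 and -0.04 in replicate 1. The first set was chosen with replicate 1 included, which favours a change there, and the second was chosen without it.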

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

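No tests in this part were chosen only after the result was seen, and the Xist values are given as measured.

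The probe set of Xist, a transcript of the inactive X chromosome of females, gave a signal outside the comparisons of the report in 2 arrays. It reached 6.37 in replicate 2 of labelled mutant saline and 5.28 in replicate 2 of control saline, and lay between 3.31 and 3.97 in the other 10 arrays. In the kainate arrays of replicate 2 it was 3.82 in control and 3.97 in labelled mutant. Whether the sex of the pooled animals differed between saline and kainate in replicate 2 was not tested. The pools contained males and females per the labels' protocols, and the sex of the animals in each pool is not given in the sources used here. Groups of 3 arrays were too small to test any 1 array against its group, and no difference of responses between genotypes passed.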

How the results depend on the processing

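The tests with replicates 2 and 3 only, the block combined with quantile normalization and the averaged comparisons were chosen only after the result was seen, and all other alternatives were chosen before the data were examined. The cause of the changes below was not tested.

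With the replicate number as a block, 37 probe sets passed for kainate in control, 23 in labelled mutant arrays, 9 for genotypes with saline, 7 with kainate, 483 for kainate and 147 for genotypes averaged, 13 rises were shared, and 13 gene groups passed in the planned comparisons against 6. In the same order of comparisons, replicates 2 and 3 only gave 637, 596, 5, 12, 1412 and 46, with 339 shared probe sets, 126 of them rises, and the block with quantile normalization gave 25, 21, 1, 8, 379 and 128, with 11 shared. For the 4 planned comparisons with a call in any setting, arrayWeights gave 254, 1169, 20 and 42, and the use of only the arrays compared gave 4, 2, 1 and 0. Quantile normalization gave 2 for genotypes with saline, and median centring gave 1 with kainate. Apart from the fits that left out 1 array, each setting with more calls for kainate kept the 10 and 11 probe sets. The difference of responses gave 0 in all settings.

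Leaving out 1 array at a time, without the block, gave 4 to 14 probe sets for kainate in control (4 without control saline replicate 1 or control kainate replicate 2, 5 without control saline replicate 3, 6 without control kainate replicate 1 or 3). It gave 6 to 17 in labelled mutant arrays (7 without labelled mutant saline replicate 2 or 3, 6 without labelled mutant kainate replicate 2 or 3, 17 without its replicate 1), 0 to 1 for genotypes with saline (1 without control kainate replicate 3) and 1 to 5 with kainate (2 without control kainate replicate 1 or 3 or labelled mutant kainate replicate 2, 1 without control kainate replicate 2 or labelled mutant kainate replicate 3). For the averaged comparisons it gave 14 to 243 for kainate, the most without labelled mutant kainate replicate 1, and 3 to 16 for genotypes, and 5 to 9 gene groups. The difference in the size of the response was -0.20 for falling probe sets (exact permutation p = 0.18), -0.025 for probe sets over 6 (exact permutation p = 0.785), -0.046 with the block (exact permutation p = 0.312), and between -0.13 without control kainate replicate 1 and 0.21 without labelled mutant saline replicate 1.

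Dusp5, Csrnp1, Spty2d1 and Rgs4 in control and Maff, Dusp5, Csrnp1, Spry2, Dusp4 and Rgs4 in labelled mutant arrays kept their calls without any 1 array. In the 12 such fits others lost them, in control Trib1 and Fosl2 in 10, Acsl4 in 8, Spry2 in 5, Maff in 4 and Ciart in 2, in labelled mutant arrays Fosl2 in 9, Ccdc86 in 8, Vgf in 7, Trib1 in 4 and Depp1 in 3, and between genotypes with kainate Nbdy in 8, Ccdc86 in 5 and Dusp4 in 4. Under median centring the adjusted p was 0.0689 for Fosl2 and 0.0665 for Acsl4 in control, 0.0723 for Fosl2 and Ccdc86 in labelled mutant arrays, and 0.0557 for Dusp4, 0.0656 for Ccdc86 and 0.111 for Nbdy between genotypes with kainate. In labelled mutant arrays, quantile normalization gave 0.0774 for Ccdc86 and 0.0507 for Fosl2, and the fit without the filter gave 0.051 for Ccdc86. Without the filter Nbdy between genotypes with kainate had 0.068. For genotypes averaged, Slc14a1 had 0.0621 without the filter, and replicates 2 and 3 only gave 0.0613 for Slc14a1, 0.072 for Plek and 0.0661 for Trmt61b. CREB target genes with kainate in control lost their call in 9 of 12 such fits (adjusted p up to 0.14), in replicates 2 and 3 only (0.236) and with the mean of all probe sets (0.106), and immediate early factors in labelled mutant arrays without the filter (0.0584). Astrocyte markers with saline lost theirs in replicates 2 and 3 only (0.0835). The difference in the size of the response changed its sign in several settings, as given above, and no named gene and no gene group with a call reversed its direction.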

Other observations

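The tests of the spiked-in controls, the activity-regulated genes in replicate 1, the Creb1 values, the neighbours of Creb1 and Crem and the oligodendrocyte markers were chosen only after the result was seen, and so were the averaged comparisons. The planned comparisons, the lists and the alternatives not named as added were chosen before the data were examined.

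In the comparison of genotypes averaged over treatments, further groups passed only with the replicate number as a block, and did not keep their call with the block and an estimated correlation. Cholesterol and lipid synthesis genes were lower (adjusted p = 0.0241 against 0.153, and adjusted p = 0.225 with an estimated correlation), with the sterol transporter gene Stard4 at -0.52. Voltage-gated ion channels were lower (adjusted p = 0.0238 against 0.107, and adjusted p = 0.223 with an estimated correlation), with the sodium channel subunit gene Scn4b at -0.56.

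With kainate averaged over genotypes, immediate early transcription factors and negative feedback genes rose (fry adjusted p = 8.47e-06 for each, and adjusted p = 0.0476 and 0.134 with the block and an estimated correlation). Of the 26 probe sets that passed, 19 were higher, and with the block 483 passed, 140 higher and 343 lower. Homer1 rose by 1.29 (adjusted p with the block = 0.00258). The receptor gene Grm5 gave -1.01 (adjusted p with the block = 0.0141), and glutamate and GABA receptors were lower as a group only with the block (adjusted p = 0.0311, and adjusted p = 0.359 with the block and an estimated correlation). The 483 probe sets were chosen with replicate 1 included, which favours the same sign there. In replicate 1, 136 of the 140 rises and 327 of the 343 falls had the same sign. Their medians there were 0.22 and -0.22, against 0.49 and -0.504 over all replicates. Among probe sets that passed in replicates 2 and 3 alone, 47.9% of rises and 61.3% of falls had the same sign in replicate 1. Some of the largest falls were small or absent in replicate 1, where Ythdf3 gave 0.25 against -2.57 and -2.90 in replicates 2 and 3, Gda 0.03 against -2.06 and -2.38, and Tmem47 0.17 against -2.48 and -2.05. Other probe sets gave smaller averaged changes, with -0.58 and -0.36 for Ythdf3, -0.22 for Gda and -0.79 and -0.48 for Tmem47.

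Pattern 1 was a broad set of changes with kainate, with 1412 probe sets passing in replicates 2 and 3, that was smaller in replicate 1, partly because these probe sets were chosen without it, with 67.9% moving the same way in its control pair (mean 0.134) and 40.8% in its labelled mutant pair (mean -0.0405). A weaker response in replicate 1 would leave its activity-regulated genes with small changes, yet 24 probe sets of such genes that rose in replicates 2 and 3 had a median change of 0.892 in replicate 1 and of 0.911 in replicates 2 and 3. An exchange of the saline and kainate arrays of labelled mutant replicate 1 is excluded by their median change of 0.885 in that pair, with 19 of 24 above 0. Differences left in the distribution of the deposited values did not account for the pattern, since 1491 probe sets passed after quantile normalization. Array medians already lay between 3.77 and 4.07 without it, so this step cannot decide about intensity effects that arose before the values were summarised. A batch of hybridization or arrays stays open, as the spiked-in bacterial controls differed between kainate and saline by -0.53 in replicates 2 and 3 (exact permutation p = 0.0286 of 70 permutations, the smallest possible, and adjusted p = 0.0858). That permutation did not keep arrays within their pairs, whose differences were -0.368 and -0.52 in control and -0.98 and -0.25 in labelled mutant pairs. The kainate minus saline difference of the spiked-in controls did not set replicate 1 apart, with 0.146 in its control and -0.403 in its labelled mutant pair (mean -0.129) against -0.25 in labelled mutant replicate 3. Their level did set replicate 1 apart, at 9.03 against 10.3 in the other arrays (exact permutation adjusted p = 0.0242). RNA quality stays open as well, since the Gapdh 3' minus 5' signal differed by 0.127 in replicates 2 and 3 (exact permutation p = 0.0286, adjusted p = 0.0858), and so does a real kainate effect that was smaller in replicate 1.

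Pattern 2 was the higher Creb1 signal in the arrays labelled mutant. An exchange of single arrays is excluded, because the smallest of the 6 differences within pairs was 0.662 and the largest 1.33. An exchange of the genotype names across all arrays could not be tested and stays open. Genes near Creb1 or Crem in the GRCm38.p6 table were not changed more often than others, with 0% of 73 neighbours within 10 Mb passing against 2.38% of the rest (Fisher's exact p = 0.42), which leaves a passenger region around the targeted alleles undecided. Where the probes lie relative to the deleted part stays open as well, and a biological reading was not tested.

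Pattern 3 was the higher signal of astrocyte and microglia markers in labelled mutant arrays. Oligodendrocyte markers did not rise with them, which argues against a lower share of neurons that raised the markers of every other cell type alike. Their median was -0.0593 over 9 genes against 0.181 for astrocyte markers (exact permutation p = 0.000162, over genes, which are not independent). Astrocyte markers were picked for their rise in these arrays, which favours such a gap, so the argument rests on the 9 oligodendrocyte genes. Endothelial and mural markers were higher with the block, as microglia markers were, and neither call was kept with the block and an estimated correlation. A lower share of neurons with unequal changes among the other cell types was not tested and stays open. Astrocyte markers were higher in 6 of 6 pairs of arrays (mean differences from 0.101 to 0.272) and microglia markers in 6 of 6 (0.151 to 0.58). A rise confined to 1 replicate number was thus not seen. These lists were singled out for being higher over the same arrays, so higher values in most pairs follow partly from that choice. A batch that followed genotype would give the same picture and stays open. What lowered principal neuron markers (adjusted p = 0.0133, and adjusted p = 0.0885 with an estimated correlation) stays open. A change within astrocytes and microglia stays open as a hypothesis as well.

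Labels of arrays were exchanged to see how many calls other groupings gave. For the genotypes averaged over treatments with the block, the real labels gave 147 and the highest other split 0 of 32 splits in all. This argues against chance but cannot exclude it. The splits were few, several counts were examined this way without adjustment, and the comparison was added after the data were seen. For kainate averaged over genotypes with the block, the real labels gave 483 and the highest other split 878, so chance is not excluded. That split exchanged the saline and kainate arrays of labelled mutant replicate 1 alone and kept the real labels in the other 5 pairs, which points to a structure of the samples, and no further split gave more than 6. For groups of 3 against 3 arrays the 10 splits are too few, with 10 and a highest other of 0 for kainate in control, 11 and 0 in labelled mutant arrays, 0 and 1 for genotypes with saline, and 4 and 4 for genotypes with kainate. For the difference of responses, 100 splits were used with the real one included, and the real labels gave 0 and the highest other split 16.

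Some groups passed in none of the 5 planned comparisons with either fit. With kainate in control animals, the adjusted p was 0.312 for clock genes, where Ciart rose, and 0.41 for choroid plexus markers, where Clic6 gave -1.54.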
